A study of Catharus ustulatus with 19 samples.

How the data were processed

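RNA was sequenced from a block of brain that held the hypothalamus and the optic chiasma of 19 captive Swainson's thrushes (Catharus ustulatus), a migratory songbird of North America. Per the labels' protocols, conditions in captivity were kept constant while day length was adjusted every week, tissue was frozen on dry ice, RNA was purified with a Trizol kit and DNase, and libraries were made with an Illumina TruSeq RNA kit. That kit does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The labels give each bird's migration status, ecotype, sex, date of collection and hour of collection after lights on. The protocol puts 10 weeks between the collections, whereas the dates of the August and October birds lie 56 to 58 days apart; the dates were used as given. The series description states that a further migratory inland bird was left out by the submitters because its expression stood apart from the rest; it was not analysed here.

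The submitters' processing notes name Trim Galore 0.3.1, TopHat2 and HTSeq, without saying what each was used for. The genome build and the gene annotation are not given in the sources used here. The authors deposited 1 table with a value per gene and bird for 11727 genes. Per the name of the deposited table, the values are counts summed over the exons of protein-coding genes and normalized by the trimmed mean of M values. The values themselves lie between 20.4 and 36 in the 19 birds, which is a log scale. The base of the logarithm is not stated; the deposited values were taken as log2, so every fold given here rests on that reading. The 19 columns hold nearly the same set of values in different orders, as quantile normalization leaves them: each has a median of 28.05, 99.3% of values occurred in at least 10 cells of the table, and the sorted columns differed at a typical rank by 0.0022. The table's column of averages equals the mean of the 19 birds within 0.0000000068 and was not used further.

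Such values no longer carry the sequencing depth, and whole read counts could not be recovered from them, so the depth of each sample is unknown and no interval for counting error is given. Making all columns alike also removes any difference in total RNA or in the overall distribution between birds. A gene can therefore only be called higher or lower relative to the other genes of the same bird. The plan made before the data were examined assumed a linear scale and a pseudocount; as the values were already logarithms, they were tested as deposited, with no pseudocount. The planned filter, a linear value of at least 0.0001% of the column's total in at least 4 birds, removed no gene.

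The genes carry identifiers of the form ENSFALG, which are paired with no names in the table. None of the 11727 identifiers matched the table of 19631 RefSeq genes supplied for the species (assembly bCatUst1.pri.v2), so it gave 0 genes a name, a function or a position. Other annotations, which may hold these identifiers, were not used. The gene lists chosen before the data were examined were therefore not tested. The rule for the genes named in the text, also chosen then, takes the smallest p-values in each direction among genes past the threshold, or the 3 smallest p-values where none passed and for the interaction and for ecotype within a status. Since it could not be applied to gene symbols, it was applied to identifiers, with at most 2 in each direction per comparison. A further gene was named after its values were seen, and is marked so.

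Birds were grouped by the labels alone into non-migratory inland (4 birds), non-migratory coastal (6), migratory inland (5) and migratory coastal (4). Each bird is a separate animal. Differential expression was tested with limma 3.58.1 in R 4.3.3: a linear model with a mean for each of the 4 groups and a term for sex was fitted to all 19 birds, and the moderated test used the mean-variance trend and robust settings. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the 11727 genes of each comparison, and a gene was called at an adjusted p under 0.05. Contrasts were migratory minus non-migratory (in inland birds, in coastal birds, their mean and their difference), inland minus coastal (in non-migratory birds, in migratory birds and their mean), and female minus male. The hour of collection was tested as a slope in the same model with the hour added. Differences are estimates of this model, adjusted for sex (for sex itself, for group), so they can depart from the difference between the plain means printed beside them. Standard errors are those of limma's moderated fit, and intervals cover 95%.

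The procedure was tested on simulated data with the real genes' means and spread, in which 200 of the 11727 genes were changed. Each gene's errors were drawn independently from a normal distribution. Real genes vary together, so the shares below hold for that setting and may differ in these birds. Changes of 0.5 log2 (1.41-fold) were called in 77% of genes for the status mean, 50% for status in inland birds, 60% for status in coastal birds, 47% for the interaction, 72% for the ecotype mean and 55% for sex. For changes of 1 log2 (2-fold) the shares were 97%, 85%, 93%, 71%, 89% and 84% in that order. Unchanged genes called in the same runs, 1 run per comparison, numbered 15, 10, 13, 9, 9 and 8. These were 7.9%, 6.9%, 7.8%, 7.1%, 5.3% and 5.4% of the calls, each above the 0.05 aimed at. For ecotype in non-migratory and in migratory birds they numbered 12 and 1, or 7.7% and 0.8%. With 1 run per comparison, a small excess over 0.05 cannot be told from chance.

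The alternatives tried were other filters, 3 ways of rescaling the columns, leaving out the sex term or the females, adding the hour, the month or, chosen after the data were seen, the day of collection (4 days), grouping by month in place of status, leaving out the 2 birds whose status differed from the other birds of their month, weighting the birds, leaving out the robust setting, fitting only the groups compared, and leaving out each bird in turn. Other splits of the birds were drawn to see how often chance gives as many genes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.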

Results

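Gene expression was measured in the hypothalamus and optic chiasma of 19 Swainson's thrushes kept in captivity and collected in 2011, on 7 and 8 August or on 3 and 4 October. The inland and coastal forms (ecotypes) of this species are known to follow different migratory routes. Of the 9 inland birds, 5 were labelled migratory and 4 non-migratory; of the 10 coastal birds, 4 were migratory and 6 non-migratory. There were 16 males and 3 females, and all the females were coastal (2 non-migratory and 1 migratory). Status nearly followed the month: 9 of the 10 birds collected in August were non-migratory and 8 of the 9 collected in October were migratory. The exceptions were migratory inland replicate 1, collected in August, and non-migratory coastal replicate 6, a female collected in October. Tissue was taken between 2.5 and 8.57 hours after lights on, at group means from 4.59 ± 1.96 hours (SD, n = 6, non-migratory coastal) to 5.22 ± 3.07 hours (SD, n = 4, migratory coastal). Values were deposited for 11727 genes on a log scale read here as log2, and the depth of the samples is unknown.

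Birds of the same group resembled each other little more than birds of different groups. Across genes, the SD of the difference between 2 birds had a median of 0.40 log2 in the 37 pairs within groups and 0.44 log2 in the 134 pairs between groups. The first principal component held 16.1% of the variance and the second 14%. Migratory coastal replicate 2 lay lowest on the first (-28.8) and non-migratory inland replicate 1 highest on the second (32.9). On the first, the coastal birds lay between -28.8 and 3.4. The inland birds lay higher, from 5.9 to 20.2, except non-migratory inland replicate 1 (-10.9) and migratory inland replicate 1 (-1). These were also the only inland birds collected on 7 August. The coastal birds of 7 August (-9.9, 3.4 and -15.5) overlapped those of 8 August (-4.3 and 1.3). Whether the day of collection set these birds apart was not tested.

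**Figure D1:**
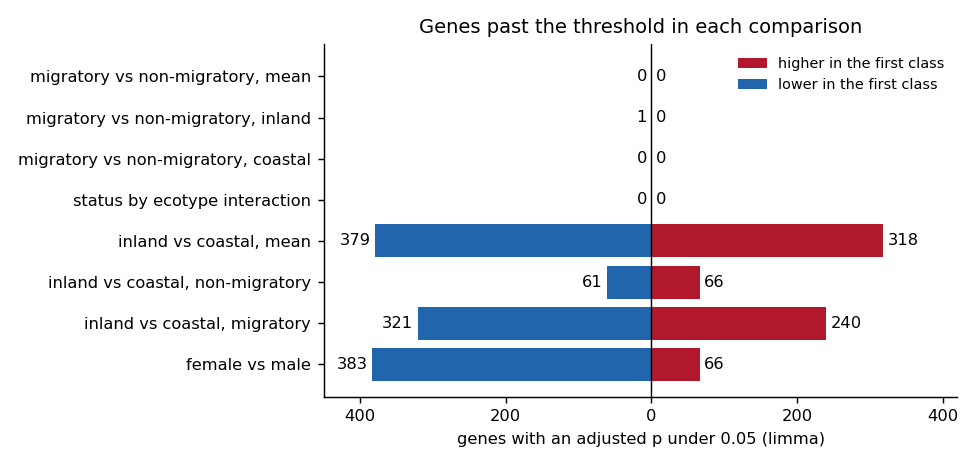
Number of genes with an adjusted p under 0.05 (limma) in each comparison of 19 birds, with genes higher in the first class named drawn to the right in red and genes lower drawn to the left in blue. Status gave 0 or 1 gene, whereas ecotype gave up to 697 and sex 449.

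The first question of the design was which genes differed between the migratory and the non-migratory state. Over both ecotypes, no gene passed the threshold with limma (smallest adjusted p = 0.26). The genes with the smallest p-values were both lower in migratory birds. ENSFALG00000005632 stood at 26.07 ± 0.33 log2 (SD, n = 9) in migratory and 26.80 ± 0.34 (SD, n = 10) in non-migratory birds, a difference of -0.76 ± 0.14 log2 (SE). ENSFALG00000013811 differed by -0.52 ± 0.10 log2 (SE). In ENSFALG00000015173, chosen after its values were seen, all 9 migratory birds (26.48 to 27.09 log2) lay above all 10 non-migratory birds (23.78 to 26.32), with a difference of 1.08 ± 0.27 log2 (SE) and an adjusted p of 0.30 by limma. It was the only gene with no overlap between the statuses, where 0.25 genes are expected by chance. At an unadjusted p under 0.05 there were 960 genes, against about 586 expected by chance. The count was 380 with the month of collection added to the model and 469 with the day added, both under 586. As status and month differ in only 2 birds, either addition would lower the count even for a real status difference. The same holds for such counts within each ecotype below. The 95% interval of the difference lay within ± 0.5 log2 for 10250 genes (87.4%) and within ± 1 log2 for 11508 genes (98.1%). For most genes measured, a difference of 2-fold or more in the mean of both ecotypes was thus outside the interval.

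In inland birds, 1 gene was lower in migratory birds and none was higher. ENSFALG00000005180 stood at 28.68 ± 0.20 log2 (SD, n = 5) in migratory and 29.42 ± 0.13 (SD, n = 4) in non-migratory inland birds. It differed by -0.74 ± 0.11 log2 (SE, 1.67-fold, 95% interval -0.97 to -0.51, limma adjusted p = 0.025), and all 5 migratory birds (at most 28.99) lay below all 4 non-migratory birds (at least 29.27). Its coastal means were 28.99 ± 0.09 (SD, n = 4) and 28.95 ± 0.24 (SD, n = 6). The difference between its inland and coastal status effects was -0.76 ± 0.15 log2 (SE), which did not pass the threshold (limma adjusted p = 0.31). There were 738 genes at an unadjusted p under 0.05 (429 with the month added, 379 with the day added and 1244 without non-migratory inland replicate 1), and 188 genes had no overlap between the statuses, where chance gives 190. The call was lost on leaving out any of the migratory inland replicates 1, 2, 4 and 5 or the non-migratory inland replicates 2 and 4 (0 genes each), and without non-migratory inland replicate 1 there were 10 calls. It was also lost with no sex term, in males only, with the month or the day of collection added, without the 2 birds whose status differed from their month, and in a fit of the inland birds alone (0 genes each). The difference of ENSFALG00000005180 itself stayed between -0.82 and -0.70 log2 leaving out each bird and between -0.76 and -0.63 in the other fits.

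In coastal birds no gene passed (limma, smallest adjusted p = 0.18), although more genes than in inland birds had an unadjusted p under 0.05 (1299, or 617 with the month added and 754 with the day added). The genes with the smallest p-values were ENSFALG00000010663, at -1.24 ± 0.21 log2 (SE) in migratory relative to non-migratory birds, ENSFALG00000001448 at 0.47 ± 0.09, and ENSFALG00000009064 at -2.43 ± 0.48. The last varied from 25.83 to 29.96 log2 among the 6 non-migratory coastal birds. In 244 genes the 4 migratory coastal birds did not overlap the 6 non-migratory ones, against 110 expected by chance, and 140 of these were higher in migratory birds. The 110 is an average over splits, and how widely this count varies between splits was not examined. Unlike the p-values, the count is not adjusted for sex. The count of called genes was 1 in a fit of the coastal birds alone and 1 or 2 without migratory inland replicate 3 or 4; ENSFALG00000010663 was called in each, with ENSFALG00000001448 in the last.

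The status effect was then compared between the ecotypes. No gene differed in its status effect with limma (smallest adjusted p = 0.31), and 1049 genes had an unadjusted p under 0.05. The smallest p-values belonged to ENSFALG00000006487 (inland effect minus coastal effect 1.02 ± 0.19 log2, SE) and ENSFALG00000004697 (-0.54 ± 0.11). Across the 11727 genes, which are not independent replicates, the inland and coastal status effects had a correlation of -0.01, and a covariance of -0.00046 against -0.00015 in simulated data with no effect. Other splits of the birds by status within ecotype gave correlations from -0.33 to 0.35, and 63 of 100 splits gave one as large. With so wide a range, the correlation near 0 does not show that the ecotypes share no status effect. The interaction was the least precise of the comparisons on status, with a 95% interval within ± 1 log2 for 10271 genes (87.6%). Without non-migratory inland replicate 1, 1 gene passed. With the month added, the correlation was 0.33, where the shared month term gave 0.52 in simulated data with no effect.

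With all birds included, ecotype was the comparison with the most genes. Over both statuses 697 genes differed between inland and coastal birds, 318 higher and 379 lower in inland birds (limma, smallest adjusted p = 1.1e-07). Most differences were small: the median size was 0.41 log2 (1.33-fold), and 63 genes differed by more than 1 log2, 23 of them higher and 40 lower in inland birds. ENSFALG00000012167 was higher in inland birds, at 29.77 ± 0.18 log2 (SD, n = 9) against 28.56 ± 0.18 (SD, n = 10) in coastal birds, a difference of 1.25 ± 0.09 log2 (SE, 2.38-fold). ENSFALG00000009884 was higher by 0.58 ± 0.04 log2 (SE, 1.5-fold). ENSFALG00000005089 was lower in inland birds, at 28.36 ± 0.09 (SD, n = 9) against 29.11 ± 0.06 (SD, n = 10), a difference of -0.72 ± 0.05 log2 (SE, 1.65-fold). ENSFALG00000010236 differed by -1.16 ± 0.08 log2 (SE, 2.24-fold). In each of these 4 genes, all 9 inland birds lay on one side of all 10 coastal birds. Such a complete separation was found in 96 genes, 59 higher and 37 lower in inland birds, where chance gives 0.25 genes; 93 of the 96 were among the called genes. Leaving out migratory coastal replicate 2 lowered the count to 398, under the 420 genes then called for sex.

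**Figure D2:**
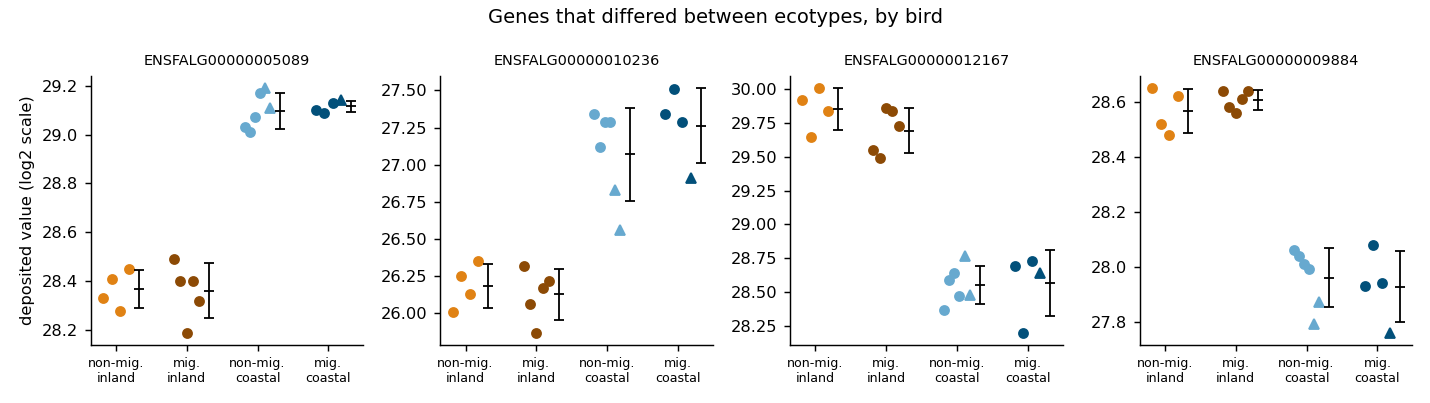
Deposited values (log2 scale) of the 4 genes named for ecotype in each of the 19 birds by group, with circles for males, triangles for females, and the mean with its SD beside each group. The inland birds lie apart from the coastal birds in each panel, in both statuses.

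Within non-migratory birds, 127 genes differed between ecotypes, 66 higher and 61 lower in inland birds (limma, smallest adjusted p = 6.9e-06). ENSFALG00000009878 stood at 25.82 ± 0.16 log2 (SD, n = 4) in inland and 27.39 ± 0.43 (SD, n = 6) in coastal birds. Its difference was -1.79 ± 0.15 log2 with the sex term (SE, 3.47-fold) and -1.57 log2 with no sex term. ENSFALG00000012167 differed by 1.34 ± 0.12 log2 and ENSFALG00000005089 by -0.71 ± 0.06 log2 (SE). The count was 49 in a fit of the non-migratory birds alone, 70 with the day of collection added and 84 without non-migratory inland replicate 2. Within migratory birds, 561 genes differed, 240 higher and 321 lower in inland birds (limma, smallest adjusted p = 4.6e-06). The smallest p-value was that of ENSFALG00000004390, at 22.16 ± 0.41 log2 (SD, n = 5) in inland and 25.89 ± 0.30 (SD, n = 4) in coastal birds. Its difference was -3.62 ± 0.30 log2 with the sex term (SE, 12.29-fold) and -3.73 log2 with no sex term. ENSFALG00000010236 differed by -1.27 ± 0.11 log2 (SE). The migratory count moved with the birds included: it was 143 without migratory coastal replicate 2, 221 without migratory coastal replicate 1, 246 without migratory inland replicate 3, 307 without migratory inland replicate 2, 331 without migratory coastal replicate 3, 373 without migratory inland replicate 4, and 1077 with birds weighted by their fit; a fit of the migratory birds alone gave 771. The interaction, which tests the difference between the statuses gene by gene, gave 0 genes.

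The ecotype differences of the migratory and the non-migratory birds went the same way. All 85 genes called in both statuses had the same direction (46 higher and 39 lower in inland birds), where independent lists of these sizes would share 1.4 higher and 1.7 lower genes. Of the 127 genes called in non-migratory birds, 126 had the same sign in migratory birds, and of the 561 called in migratory birds, 491 had the same sign in non-migratory birds. Across genes the ecotype effects of the statuses had a correlation of 0.47, against -0.37 to 0.38 in 99 other splits of the birds by ecotype within status. These comparisons use different birds. Their effects share the sex term, and their tests share each gene's estimate of spread. A shared spread can bring the same genes into both lists, so the overlap of independent lists is a low yardstick. In simulated data with no effect the sex term gave a correlation of 0.08 and a covariance of 0.0032, against an observed covariance of 0.037. In males alone, where the effects share no term, the correlation was 0.34 (-0.32 to 0.25 in 99 other splits of the males). All 71 genes called in both statuses in males (of 108 and 784) had the same direction, though these tests still shared the spread.

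**Figure D3:**
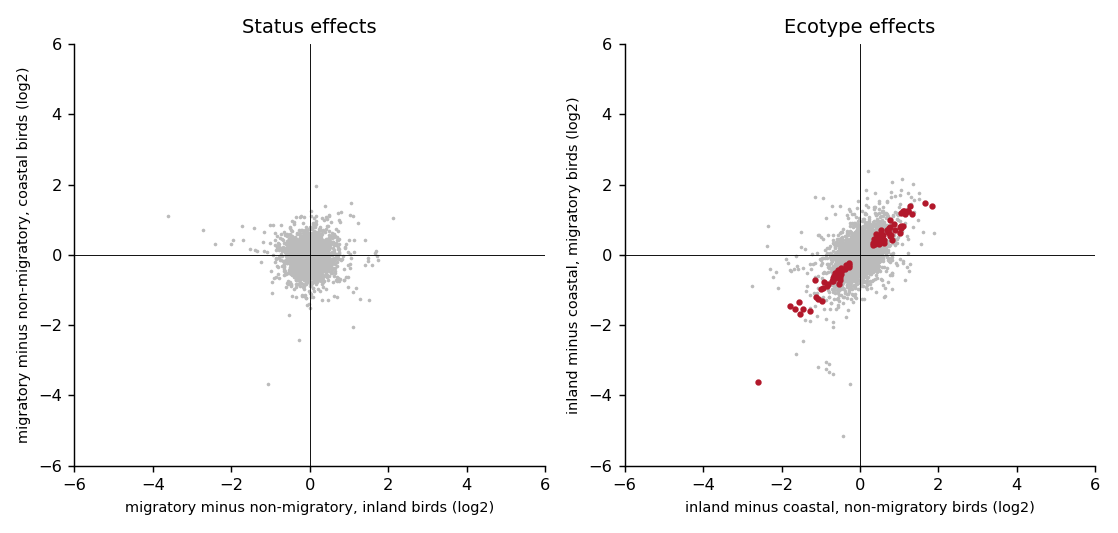
Differences of all 11727 genes (log2), for status in inland birds against coastal birds (left) and for ecotype in non-migratory birds against migratory birds (right), with genes called in both sets of birds in red. The status effects form a cloud with no slope (correlation -0.01, against -0.33 to 0.35 in other splits of the birds). The ecotype effects lie along a rising line (0.47) with 85 genes called in both.

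Sex was compared as a check of the labels and because it entered the model. Most of the 449 genes called were lower in females, 383 against 66 that were higher (limma, smallest adjusted p = 7.4e-09). The lower genes differed by similar amounts: the median was -0.78 log2 (1.72-fold), the quartiles were -0.96 and -0.58, and 353 of the 383 (92.2%) lay between -1.2 and -0.3. The higher genes had a median of 0.36 log2. ENSFALG00000010416 stood at 28.98 ± 0.08 log2 (SD, n = 3) in females and 29.88 ± 0.08 (SD, n = 16) in males, a difference of -0.89 ± 0.05 log2 (SE, 1.85-fold), and ENSFALG00000009086 differed by -0.98 ± 0.06 log2. ENSFALG00000002143 was higher in females by 0.55 ± 0.06 log2 and ENSFALG00000008864 by 1.53 ± 0.19 log2 (SE). In these 4 genes no female overlapped any male. That was so in 414 genes, 337 of them lower in females, against 24 expected by chance. The count of higher genes was the less stable: it was 28 without migratory coastal replicate 4, 33, 37 and 43 without non-migratory coastal replicates 6, 5 and 3, 33 with the month added, 18 with the day added (298 genes in all), 44 with median-of-ratios rescaling and 32 without the 2 birds whose status differed from their month, while 280 or more genes were lower in each of these. The 3 females were all coastal, so the sex difference was in effect measured among coastal birds.

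**Figure D4:**
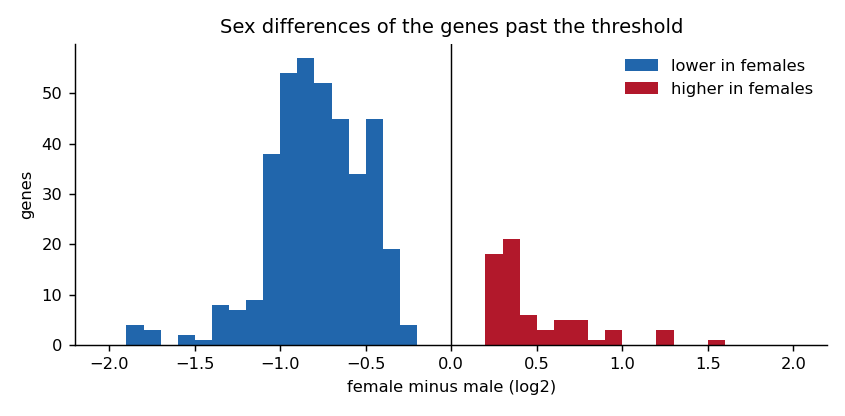
Histogram of the female minus male difference (log2, bins of 0.1 log2) of the 449 genes called for sex, from the fit of 3 females and 16 males. The 383 genes lower in females gather around a median of -0.78, and the 66 higher genes around 0.36.

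The labels give the hour at which each bird was taken, and it was tested as a slope. Over 2.5 to 8.57 hours after lights on, 11 genes changed with the hour, 5 rising and 6 falling (limma, smallest adjusted p = 0.00053). ENSFALG00000004057 fell by 0.21 ± 0.02 log2 per hour (SE), 2.38-fold over the span of 6.07 hours. ENSFALG00000011294 changed by -0.12 ± 0.02 log2 per hour, or 1.63-fold over the span (adjusted p = 0.0048). ENSFALG00000011946 rose by 0.06 ± 0.01 log2 per hour and ENSFALG00000002003 by 0.13 ± 0.02 (limma adjusted p = 0.018 each). In each of these 4 genes the slope had the same sign in all 4 groups, but the genes were picked for their slope within these same groups. A straight line was fitted, and each bird gave 1 time point. The count was 1 without non-migratory coastal replicate 5, 6 without migratory inland replicate 1 or migratory coastal replicate 1 or 2, 7 without non-migratory inland replicate 3, and 17 without migratory coastal replicate 4. It was 3 in males only, 7 with no sex term and 4 without the 2 birds whose status differed from their month. Sex and hour overlapped in part: the females were taken at 2.65, 7.55 and 8.57 hours. The early female was non-migratory coastal replicate 5, so without it only late females remained. Whether this overlap lowered the count was not tested. Among the named genes, ENSFALG00000004057 was called in all 19 fits that left out 1 bird, and ENSFALG00000011294 in 18, its call being lost without non-migratory coastal replicate 5. Each of the rising genes lost its call in 4 of the 19: without migratory inland replicate 1, non-migratory coastal replicate 5 or migratory coastal replicate 1 for both, without non-migratory inland replicate 3 for ENSFALG00000011946 and without migratory coastal replicate 2 for ENSFALG00000002003. Both were also lost in males only, with no sex term, with the day added and without the 2 birds, and ENSFALG00000011946 with the month in place of status.

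**Figure D5:**
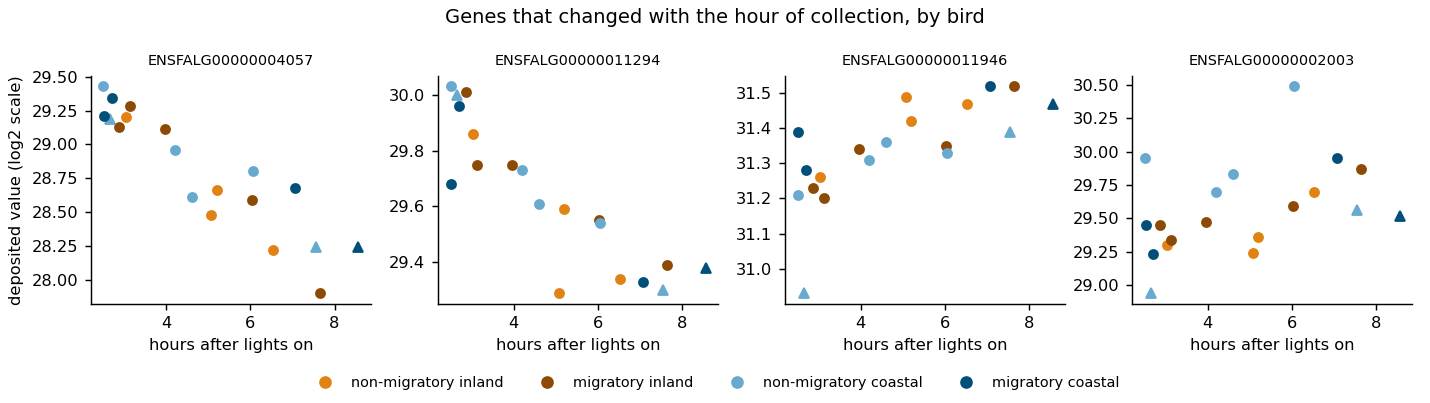
Deposited values (log2 scale) of the 4 genes named for the hour of collection in the 19 birds against hours after lights on, coloured by group, with circles for males and triangles for females. The first 2 panels fall and the last 2 rise across birds of all 4 groups.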

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

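Within the 4 groups, 7 values of the named genes lay far from the other birds of their group, out of 100 tests of a group on a gene or a principal component; about 1 in 20 such tests is passed by chance, or 5 here. The tests were planned, but ENSFALG00000015173 was chosen after its values were seen.

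Migratory coastal replicate 4 stood apart in 3 genes named for sex, at 28.94 log2 in ENSFALG00000010416 (the other 3 birds from 29.71 to 29.75), 27.77 in ENSFALG00000009086 (28.68 to 28.84) and 30.36 in ENSFALG00000002143 (29.69 to 29.76). It was the only female in its group, and the genes were picked for their sex difference.

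ENSFALG00000015173 had an isolated bird in 3 groups. It stood at 25.03 log2 in non-migratory inland replicate 1 (the others from 25.92 to 26.03), 23.78 in non-migratory coastal replicate 2 (25.45 to 26.32) and 27.03 in migratory inland replicate 3 (26.67 to 26.73). Its status difference was 0.88 log2 without non-migratory coastal replicate 2, against 1.08 with all birds. ENSFALG00000004390 stood at 24.99 log2 in non-migratory coastal replicate 4, with the other 5 birds from 25.66 to 26.05; all the coastal birds were still above the inland birds, which reached 23.44.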

How the results depend on the processing

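The alternatives for counts and named genes were chosen before the data were examined, except adding the day of collection and those for ENSFALG00000015173 and both correlations of effects, which were chosen after seeing the data. The status mean gave 0 genes in every alternative run. The count for sex (449) was 298 with the day added and 322 to 471 leaving out each bird; of these, the genes higher in females (66) fell to 18 with the day added, 44 with median-of-ratios rescaling and 28 without migratory coastal replicate 4. The inland status count of 1 was 0 with no sex term, in males only, with the month or day added, without the 2 birds whose status differed from their month and in a fit of the inland birds alone, and 0 to 10 leaving out each bird, while the difference of ENSFALG00000005180 stayed between -0.82 and -0.63 log2. The coastal status count of 0 was 1 in a fit of the coastal birds alone and 0 to 2 leaving out each bird, and the interaction 0 to 1. The ecotype mean of 697 gave 607 with the day added, 476 of them shared, and 398 to 779 leaving out each bird. Ecotype in non-migratory birds (127) gave 49 in a fit of those birds alone, 70 with the day added and 84 to 141 leaving out each bird. Ecotype in migratory birds (561) gave 1077 with weighted birds, 559 of them shared, and 143 to 789 leaving out each bird, 140 of the 143 shared. The hour count of 11 was 7 with no sex term, 3 in males only, 4 without the 2 birds and 1 to 17 leaving out each bird. The correlation of status effects (-0.01) was 0.33 with the month or the day added (0.52 in simulated data with no effect and the month) and -0.06 to 0.04 leaving out each bird; that of ecotype effects (0.47) was 0.34 in males and 0.34 to 0.51 leaving out each bird. Apart from the fewer birds these fits hold, the cause was not tested. For named genes, 884 alternative values were computed: 849 kept their direction and side of the threshold, 31 lost a call, 4 gained one and 0 changed direction.

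The planned change of pseudocount did not apply to values that are already logarithms, the count test was not run because whole reads could not be recovered, the tests of gene lists were not run, and the correlation over called genes only was not computed, as status called 1 gene. Leaving out the filter changed nothing, since it removed no gene, and the 3 rescalings moved column medians by at most 0.021 log2, so they test the authors' normalization little, though not without effect on the genes higher in females. The replicate numbers are names in accession order and gave no pairs. Depth is unknown, so how far it limits genes with low values was not tested.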

Other observations

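The tests in this part that were chosen only after the results were seen are those on sets of variable genes, on held-out ecotype scores, on counts at an unadjusted p, on splits of the males, on splits for ecotype within a status and for sex, on the hour for ecotype, and on the larger ecotype count in migratory birds.

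Some genes varied far more between birds of one group than the rest. The SD within groups, after the sex term, was above 1 log2 in 94 genes (0.8%), against a median of 0.17 log2 over all genes. Of these 94 genes, 55 fell into 4 sets of at least 8 genes that varied together (mean correlation of at least 0.6 for joining). With each gene's values shuffled over the birds, 100 times, the largest set had 3 genes. A set of 8 genes had a median correlation of 0.96 and spanned 6.9 log2 (119-fold) between birds. Its mean was highest in non-migratory inland replicate 2, at 3.7 log2 above the average bird, and lowest in migratory inland replicates 2 and 3, at -3.2 each. In this set every migratory inland bird lay below the average (-3.2 to -0.7), while migratory coastal replicates 1 to 4 stood at 1.6, -1, 2.6 and 2.8. Non-migratory birds of each ecotype lay on both sides. A set of 21 genes was lowest in non-migratory inland replicate 1 (-3.1) and migratory coastal replicate 2 (-2.2), the extreme birds of the principal components. A set of 9 genes was lowest in non-migratory inland replicate 1 (-2.4), followed by migratory coastal replicate 2 and non-migratory coastal replicate 1 (-2.0 each). In this set the birds of 7 August stood at -2.4, -2.0, -0.7, 0.2 and -1.4. Those of 8 August stood at 0.5, 1.3, 1.4, -0.3 and 1.4, while the birds of 3 and 4 October overlapped. A link of this set with the day of collection was not tested. A set of 17 genes ran from -2.7 in non-migratory coastal replicate 2 to 2.2 in non-migratory inland replicate 1. None of the 55 genes was called for status or for the ecotype mean with limma. As these genes were picked for a large spread within groups, a call was unlikely whatever their link to the groups. With no gene names, the cell types or regions these sets belong to were not examined.

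Ecotype could be read from a bird that took no part in choosing the genes. On a score built from the other 18 birds over 200 genes, with inland birds at 1 and coastal birds at -1, all 19 birds fell on their own side, the 9 inland birds from 0.35 to 1.19 and the 10 coastal birds from -1.36 to -0.53. The inland bird nearest to the coastal side was non-migratory inland replicate 1.

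The first pattern weighed is the near absence of genes called for status: a count of 0 is reached by any split, so the 100 of 100 found over both ecotypes (highest other 7), in coastal birds (highest other 2) and for the interaction (highest other 4) test nothing, while 10 of 100 splits of inland birds gave 1 gene or more (highest other 3), so chance cannot be excluded for the called gene. At an unadjusted p, 10 of 100 splits gave as many genes as the mean (960, highest other 1301), 36 of 100 as the inland birds (738, highest other 1268) and 10 of 100 as the interaction (1049, highest other 1400). For the coastal birds, 4 of 100 gave as many (1299, highest other 1612), with no correction for having looked at 4 counts. With the month added the coastal count was 617, near the 586 expected by chance, but the month nearly repeats the status and would lower the count even for a real status difference. Whether the month rather than the status label orders the birds cannot be told apart: on a status score built from other birds, the migratory bird of August had -0.23 and the non-migratory bird of October 0.04, but only 11 of the other 17 birds fell on their own side, with means of 0.29 ± 0.43 (SD, n = 8) for migratory and -0.07 ± 0.62 (SD, n = 9) for non-migratory birds. Grouping by month in place of status called 0 genes over both ecotypes, with 1105 at an unadjusted p under 0.05, and in inland birds 1 gene other than the one called by status, and with the month beside status the unadjusted counts for status fell to 380 (mean), 429 (inland) and 617 (coastal), which does not separate the labels either, as they differ in only 2 birds. With the hour of collection added, the inland gene was still called, at -0.74 log2 as before; over both ecotypes the hour could not be tested as a cause, with 0 called genes to lose.

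The second pattern is the 697 genes called for ecotype. Chance can be excluded: 1 of 100 splits by ecotype within status, the real one, gave as many (highest other 2), and likewise 1 of 100 for non-migratory birds (127, highest other 43) and 1 of 100 for migratory birds (561, highest other 84). At an unadjusted p, 1 of 100 splits gave as many for the mean (2480, highest other 1523) and for migratory birds (2564, highest other 2151), but 7 of 100 for non-migratory birds (1315, highest other 1670), so chance is not excluded for that last count. The tables argue against the sex of the coastal females, since a fit of the 16 males called 723 genes, as many as in 1 of 100 splits of the males (highest other 255), whereas the 100% of the 697 genes with an unadjusted p under 0.05 in the same direction in males adds little, as the sex term already leaves the difference to the males, and with no sex term 443 of the 697 were called; they also argue against the hour, since 96% were still called with the hour in the model. With the month added 653 genes were called, 619 of them among the 697. With the day of collection added there were 607, of which 476 were among the 697. The day can therefore not be set aside for the rest of the 697. What also stays open is a difference between ecotypes in the reads' match to the reference or in the composition of the dissected block. A difference in the birds' history before capture stays open as well. None of these could be tested, and a difference in gene regulation between the ecotypes was not tested either.

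The third pattern is the larger number of ecotype genes in migratory (561) than in non-migratory birds (127), a difference of 434 and a ratio of 4.42. In other fits it was 771 against 49 (only the groups compared), 784 against 108 (males) and 1077 against 117 (weighted birds), and a change of 0.5 log2 was called in 43% of simulated genes in migratory and 52% in non-migratory birds (1 and 12 false calls). Only 2 of 100 splits of the birds by status within ecotype, the real one included, gave as large a difference (highest other 535), which argues against chance. A candidate explanation is migratory coastal replicate 2, the extreme bird of the first principal component, which also had the lowest ecotype score (-1.36). Without it the ratio was 1.2 (143 against 119 genes), whereas the ratio stayed between 1.99 and 7.04 when any of the other 18 birds was left out. The bird was singled out after the results were seen, so these ratios describe how far the count rests on it but do not test it as a cause. As the interaction called 0 genes, a seasonal change in the ecotype difference stays open.

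For sex, 1 of 100 splits of the coastal birds gave as many as the 449 called genes (highest other 18), which excludes chance, and 1 of 100 as many as the 1575 at an unadjusted p under 0.05 (highest other 1504), a count that was 943 with the day added. The 383 genes lower in females gathered near -0.78 log2 and the genes' positions are not known here. Female birds carry a single Z chromosome and males a pair; whether the 383 genes lie on it was not tested.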
